A study of Arabidopsis thaliana with 59 samples.

How the data were processed

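The series measured small RNA in the aerial parts of Arabidopsis thaliana plants of 15 genotypes, with 59 libraries. Per the labels, RNA was extracted with a miRNeasy kit, libraries were made with a NEBNext small RNA kit and sequenced on an Illumina HiSeq. Reads were mapped to TAIR10 with Bowtie 1.2.2 and handled with SAMtools 1.9, per the submitters' processing notes. The values used here are of 22-nt reads per gene.

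The authors deposited 1 table of 32420 genes, of which 32375 have values. It holds for each of 15 genotypes the mean signal of 22-nt reads over its libraries, called TPM per the file headers. The column sums differ more than 10-fold, so the denominator of this signal is not known, and the text calls the values units. The deposited table also holds for 8 comparisons the log2 fold, the p-value and the adjusted p-value, which the authors computed with DESeq2 per the submitters' processing notes. The planned tests assumed read counts per library, and the table holds means of scaled signal instead, so a test for continuous values was used. How reads that map to several genes, or to either strand, were counted is not stated, so genes with near-identical copies and overlapping genes are uncertain.

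Values per library were recovered from the means. Each mean of 4 libraries is a sum of whole reads, each multiplied by a step that is particular to the library, and the steps were estimated from genes with few reads. Libraries are named A to D in the order of these steps. A mean was accepted where 1 combination of reads alone matched it within 1.0 unit of its last printed digit, and tolerances of 0.6 and 1.6 were tried before this was settled. Means up to 400 mean steps were searched, and up to 3000 in columns printed in full precision. Recovery succeeded for 97.9 to 99.9% of genes per genotype. Genes with means above 52.5 units in ein5-1, the lowest limit, and above 355 units in ski2-2 dcl4-2 ago1-27, the highest, could not be recovered and are outside the limma tests. A gene was tested only where it was recovered in each group compared. Limits differ, as 52.5 units in ein5-1 against 94.4 in Col-0 and 99.7 in ein5-1 dcl2-1. Genes higher in the group with the higher limit are thus kept more often, which tilts the split of higher and lower genes and the choice of named genes. On simulated means of 12000 genes, 97.4% were recovered with 10 printed digits and 99.3% in full precision, with 0 wrong among those recovered. No pair of libraries within a genotype was alike to within sampling noise. The spread, as chi-square per gene, was uneven. In ein5-1 dcl4-2 dcl2-1 it was 1.48 between libraries A and B and 1.99 between C and D, but 2.31 to 2.46 across these pairs. It was 1.84 to 2.31 in ein5-1 dcl4-2 ago1-27, 1.76 to 1.93 in ski2-2 dcl4-2 ago1-27 and 1.17 to 1.63 in the other genotypes. The denominators implied by the steps lie between 210875 and 3027589 reads.

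Library values were compared with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(units + 1). Genes with a mean of at least 1 unit over the libraries compared were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each test used the libraries of the groups compared, in 16 comparisons and 2 interactions, and in 2 comparisons of ago1-45 with ago1-27 added after the values were seen. The p-values measure the spread between libraries of a genotype and nothing beyond it. On simulated data for dcl2-1 against Col-0, with 50 genes changed per size, 12% of 2-fold, 68% of 4-fold and 100% of 8-fold rises were called and 4 unchanged genes were called. For ski2-2 dcl4-2 against Col-0, 0%, 48% and 90% of such rises were called. Falls of 8-fold were called in 50% and 26% of cases, so a missing call says little for small rises and for falls of up to 8-fold.

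Most genes named in the text were chosen by a rule fixed before the data were examined. AT2G01021, AT3G06435, the genes of the other observations and the values of named genes in further genotypes were chosen after their values were seen. The rule takes the 10 higher and the 10 lower genes of each comparison with the largest difference in mean, at adjusted p below 0.05, a log2 fold of at least 1 and libraries that do not overlap. It takes 5 and 5 for single mutants, double mutants with dcl2-1 and triple mutants with ago1. The fixed lists and the mutated genes are named as well, and the text names a part of all these. For the authors' deposited comparisons, genes whose recovered libraries overlap were left out, and genes without recovered libraries were kept, so that part of the rule was not applied to the latter. The 11 lists are 2 nitrate reductases, 12 nitrate uptake and assimilation genes, 8 SMXL genes, 8 trans-acting siRNA loci, 27 protein-coding loci of phased siRNAs, 48 targets of conserved microRNAs, 18 factors of RNA silencing and decay, 20 photosynthesis genes, 12 stress and abscisic acid genes, 10 anthocyanin genes and 10 floral markers. Annotated microRNA loci (178), chloroplast genes (88) and mitochondrial genes (122) were counted as classes. Each list was also adjusted over its own members alone.

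Differences between the ein5-1 and ski2-2 backgrounds were tested on log2 folds of the authors' deposited table, with the standard error of each fold taken from its p-value (an upper limit where that is listed as 0), and again after each set of folds was centred on its median. Overlaps of gene lists were tested with the Fisher exact test in SciPy 1.17.1. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 were used for the other steps. Gene symbols, classes and 22-base words came from the TAIR10.1 annotation, with 97.9% of genes matched by name. Coordinates served only to cut the words from each exon, so words across splice junctions are missing.

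Alternatives were a pseudocount of 0.1, quantile normalization, scaling by the sum over microRNA loci, no filter on low values, all 59 libraries fitted together and each library left out in turn. Further ones, chosen after the data were seen, were the calls of the authors' deposited table, its folds centred on their median, and ein5-1 dcl2-1 without libraries C and D. The genes of highest value, NIA1 and NIA2 among them, have no recovered libraries in the double mutants, so their shares of the column sums are given without a test.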

Results

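Small RNA was sequenced from the aerial parts of 20-day-old Arabidopsis thaliana plants, grown for 6 days on MS medium and 14 days on soil. The 59 libraries cover 15 genotypes, with 4 libraries each in 14 of them and 3 for ski2-2 dcl4-2 ago1-27. DCL2 and DCL4 are Dicer-like enzymes, of which DCL2 makes 22-nt siRNAs. EIN5 (also called XRN4) is the cytoplasmic exoribonuclease that degrades mRNA from the 5′ end, SKI2 is an RNA helicase that serves the exosome at the 3′ end, and AGO1 is the main effector of plant microRNAs and siRNAs. Col-0 is the wild type. The genotypes ask which mRNAs give rise to 22-nt siRNAs when mRNA decay and DCL4 are both lost, and whether DCL2 and AGO1 are needed.

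The authors' table gives for each of 32375 genes and each genotype the mean of 22-nt reads in scaled units. The means of all genes add up to between 142140 and 289411 units in 13 genotypes, to 967422 in ski2-2 dcl4-2 and to 1906264 in ein5-1 dcl4-2. Values of single libraries were recovered from these means for 97.9 to 99.9% of the genes of a genotype and were compared with limma on log2(units + 1). The genes of highest value could not be recovered and are taken from the authors' deposited table. A library holds between 21765 and 298481 recovered reads, and 1 read is worth 0.330 to 4.74 units. The libraries are therefore shallow, and many low genes rest on 1 read or none. For each gene named with a limma fold, other than the interactions, the libraries of the 2 groups do not overlap. Adding 1 unit tends to make the limma folds of low genes smaller than the ratio of their means. These folds are differences of mean logs, so they can also exceed that ratio where libraries are uneven.

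Over the mutated genes themselves few 22-nt reads were found. The authors' means at DCL2, DCL4, XRN4 and SKI2 lay between 0 and 6.08 units in all 15 genotypes, so these counts of small RNA do not check any label. AGO1 had an authors' mean of 10.4 units in Col-0, 27.1 in dcl4-2, 29.95 in ein5-1 dcl4-2 and 124 in ski2-2 dcl4-2.

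When DCL4 was lost together with EIN5 or SKI2, 22-nt reads piled up on NIA1 and NIA2, which encode the nitrate reductases that begin nitrate assimilation. The authors' mean of NIA1 was 57.9 units in Col-0, 64.3 in dcl4-2, 77.3 in ein5-1 and 187 in ski2-2, and it was 393891 in ein5-1 dcl4-2 and 198967 in ski2-2 dcl4-2. NIA2 had 77.2 units in Col-0 by the authors' means, 93.5 in dcl4-2, 107 in ein5-1 and 239 in ski2-2, against 374800.0 in ein5-1 dcl4-2 and 168986 in ski2-2 dcl4-2. Both nitrate reductase genes, 2 of 2 on their list, have adjusted p below 0.05 in each double mutant against Col-0 in the authors' deposited table, and NIA1 and NIA2 made up 40.3% of the summed means in ein5-1 dcl4-2 and 38.0% in ski2-2 dcl4-2, and between 0.0110 and 0.265% in the other genotypes. The 10 genes of highest value held 59.6% in ein5-1 dcl4-2, 68.8% in ski2-2 dcl4-2, 47.8% in ein5-1 dcl4-2 ago1-45 and 17.7 to 30.6% elsewhere. Without structural RNA, organelle and microRNA loci, NIA1 and NIA2 held 41.2% and 40.3% in these 2 double mutants.

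**Figure D1:**
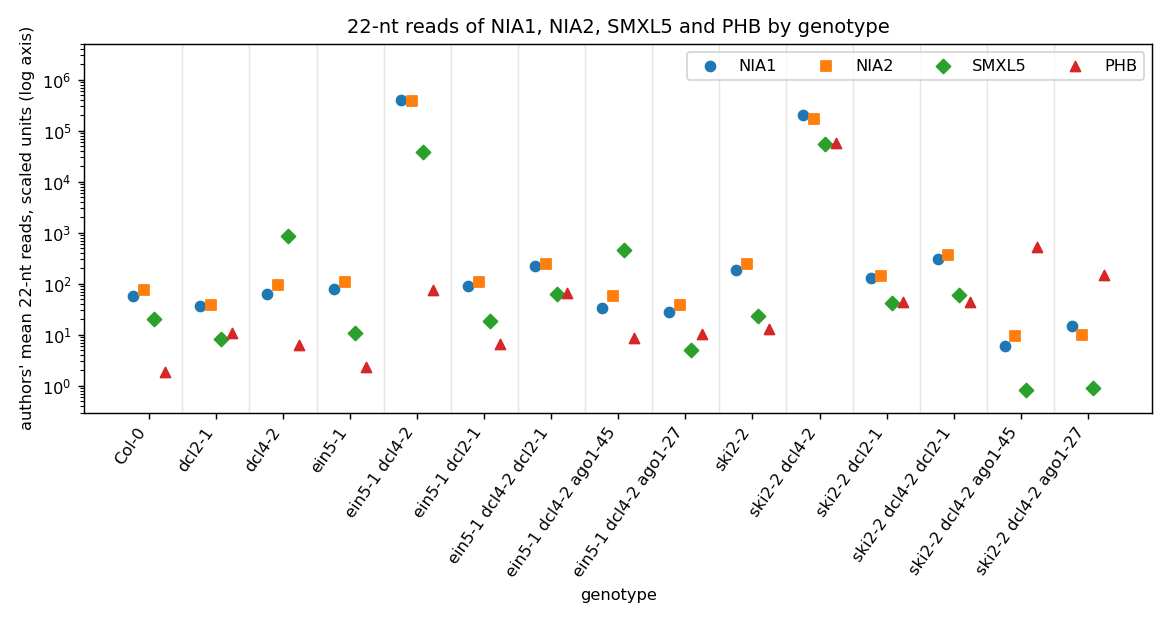
Authors' means of 22-nt reads on NIA1, NIA2, SMXL5 and PHB in each of 15 genotypes, in scaled units on a log axis. Each point is the mean of 4 libraries (3 for ski2-2 dcl4-2 ago1-27) as given in the deposited table.

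In ein5-1 dcl4-2, reads also rose on GTE7, DGAT3, SMXL5, HSP70 and other genes. After NIA1 (log2 fold over Col-0 12.43) and NIA2 (11.94), the authors' deposited table puts the bromodomain genes GTE7 (9.89) and GTE2 (9.69) and the acyltransferase gene DGAT3 (10.79) among the genes of highest value. SMXL5 (10.54), a gene of phloem formation, and the chaperone genes HSP70 (13.82) and HSC70-1 (8.12) follow in the authors' deposited table. CYP79B2, which makes precursors of indole glucosinolates, rose by 13.43 and GAE6, an epimerase for pectin sugars, by 9.28 according to the authors' deposited table. The adjusted p of these 10 genes in the authors' deposited table is at most 9.25e-172, and HSP70 and CYP79B2 came from authors' means of 1.89 and 2.06 units in Col-0 to 35301 and 30250 units. Against ein5-1 alone the authors' deposited table gives log2 folds of 12 for NIA1, 11.45 for NIA2, 11.23 for GTE7 and 11.44 for SMXL5. GAE6 already had 925 units in ein5-1 by the authors' means, and its fold over ein5-1 in the authors' deposited table is 4.57. Against dcl4-2, the authors' deposited table has NIA1 at 12.27, NIA2 at 11.66 and SMXL5 at 5.13, because SMXL5 had 879 units in dcl4-2.

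Reads fell on AT1G63080, ATCG00490 and others. Lower genes were chosen by the difference in mean, which favours RNAs with many reads in the wild type, and AT3G06435, which has more, went from an authors' mean of 6520.2 to 6820.35 units. In the authors' deposited table the pentatricopeptide repeat genes AT1G63080 and AT1G63400, known sources of secondary siRNAs, fell by 4.48 and 4.44 log2 in ein5-1 dcl4-2 against Col-0 (adjusted p 2.4e-173 and 8.3e-163). The authors' means of these genes went from 858 to 47.2 and from 821 to 45.4 units, and dcl4-2 alone already had 36.8 and 27.0. The large subunit gene of Rubisco, ATCG00490, fell by 2.83, the light-harvesting gene LHCB1.3 by 1.58 and MIR319a, whose product acts on TCP factors, by 1.87 in the authors' deposited table. Against ein5-1, AT1G63080 changed by −4.25, AT1G62914 by −4.33 and the aspartate kinase gene AK3 by −3.26 in the authors' deposited table.

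Among genes below the range of NIA1, recovered libraries show the same wide rise in ein5-1 dcl4-2. GDH2, a glutamate dehydrogenase gene, had 97.1 units against 1.41 in Col-0 (limma log2 fold 5.52, SE 0.38, adjusted p 1.2e-10). LDOX, which acts late in anthocyanin synthesis, had 99.1 against 4.47 units (4.54, SE 0.39, limma adjusted p 3.1e-09). The glucosinolate myrosinase gene TGG1 fell by 1.31 log2 (SE 0.16, limma adjusted p 7.2e-07) and the photosynthetic genes GAPA-2 and PSAG by 2.37 (SE 0.27) and 1.70 (SE 0.23). Against ein5-1, limma gives 4.87 (SE 0.32) for GDH2, 3.92 (SE 0.23) for PCK1 of gluconeogenesis, 4.32 (SE 0.27) for the fatty acid elongase gene KCS8, and −1.3 (SE 0.21) for the glycosyltransferase gene GT18. All 4 adjusted p of these limma tests are at or below 1.2e-05.

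The median log2 fold of all genes in ein5-1 dcl4-2 against Col-0 is 0.93 in the authors' deposited table and 0.90 in limma. With limma, 5724 of 16961 genes changed against Col-0, 5179 higher and 545 lower, and 5554 of them by a factor of 2 or more. Quantile normalization turns this split to 2072 higher and 2648 lower, so most of the 5179 genes are not called higher once the general rise is taken out. The authors' deposited table has 4418 genes higher and 930 lower, and 2190 and 2946 when its folds are centred on their median. Against ein5-1, the limma median is 0.86 and 5127 genes were higher and 543 lower, of 16838. Quantile normalization makes these 1866 and 2515, microRNA loci as the scale 3929 and 1113, and centred folds of the authors' deposited table make them 1957 and 2813. NIA1, GTE7, HSP70 and the other genes named above lie far from this shift.

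In ski2-2 dcl4-2, NIA1 and NIA2 were followed by GLT1 and by PHB, REV, ATHB8 and PHV, which pattern leaves and vessels. The authors' deposited table gives log2 folds over Col-0 of 11.55 for NIA1, 10.90 for NIA2 and 11.99 for GLT1, the NADH-dependent glutamate synthase gene. The class III homeodomain-leucine zipper genes PHB, REV, ATHB8 and PHV, which microRNA miR166 targets, rose by 14.23, 14.03, 14.44 and 12.51 in the authors' deposited table. Their authors' means went from 1.83, 1.88, 0.768 and 2.08 units in Col-0 to 56875, 51142, 26908 and 15586. SMXL5 (11.23), its relative SMXL4 (10.08) and the chlorophyll synthesis gene GUN5 (5.91) complete these 10 genes in the authors' deposited table, with adjusted p of at most 7.4e-121. Against ski2-2, NIA1 rose by 9.89, NIA2 by 9.31, PHB by 11.82, ATHB8 by 13.25 and GUN5 by 6.48 in the authors' deposited table. Against dcl4-2 the authors' deposited table lists 11.39 for NIA1, 10.62 for NIA2, 5.84 for SMXL5 and 6.39 for SMXL4.

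Lower in ski2-2 dcl4-2 than in Col-0 were again AT1G63080, by 2.47 (161 units by the authors' means, against 36.8 in dcl4-2 alone), and ATCG00490, by 1.56, with RCA, the Rubisco activase gene, by 2.12 and MIR159b, which acts on GAMYB genes, by 1.59 in the authors' deposited table. AK3 fell from an authors' mean of 561 units in ski2-2 to 21.6, by 4.74 log2 in the authors' deposited table. Recovered libraries put AGO1 at 124 units against 10.4 in Col-0 (limma log2 fold 3.48, SE 0.23, adjusted p 2.3e-22). P5CS1 of proline synthesis (4.18, SE 0.31), the beta-glucosidase gene PYK10 (4.8, SE 0.39) and APR3 of sulfate reduction (4.03, SE 0.34) rose with limma adjusted p of 3.1e-19, 1.5e-17 and 1.7e-16. TGG1 and the phosphoglycerate kinase gene PGK1 fell by 1.17 (SE 0.16) and 2.04 (SE 0.28). Against ski2-2, AGO1 rose by 2.44 (SE 0.21), P5CS1 by 5.49 (SE 0.42) and PYK10 by 5.33 (SE 0.43), while the carbonic anhydrase gene CA1 fell by 3.01 (SE 0.29) and the plastocyanin gene DRT112 by 1.76 (SE 0.21).

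With limma, 1395 of 12440 genes changed between ski2-2 dcl4-2 and Col-0, 802 higher and 593 lower. A pseudocount of 0.1 gives 568 and 331, quantile normalization 677 and 839, microRNA loci as the scale 467 and 1129, and the calls in the authors' deposited table are 982 and 935. Against ski2-2 there were 767 higher and 747 lower of 12919 genes, 488 and 431 with a pseudocount of 0.1, and 389 and 1401 on the scale of microRNA loci. The median log2 fold of all genes in the authors' deposited table is 0.00 for each ski2-2 dcl4-2 comparison, so the general rise of ein5-1 dcl4-2 has no counterpart here. AGO1, P5CS1 and PYK10 keep their direction under each scale.

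**Figure D2:**
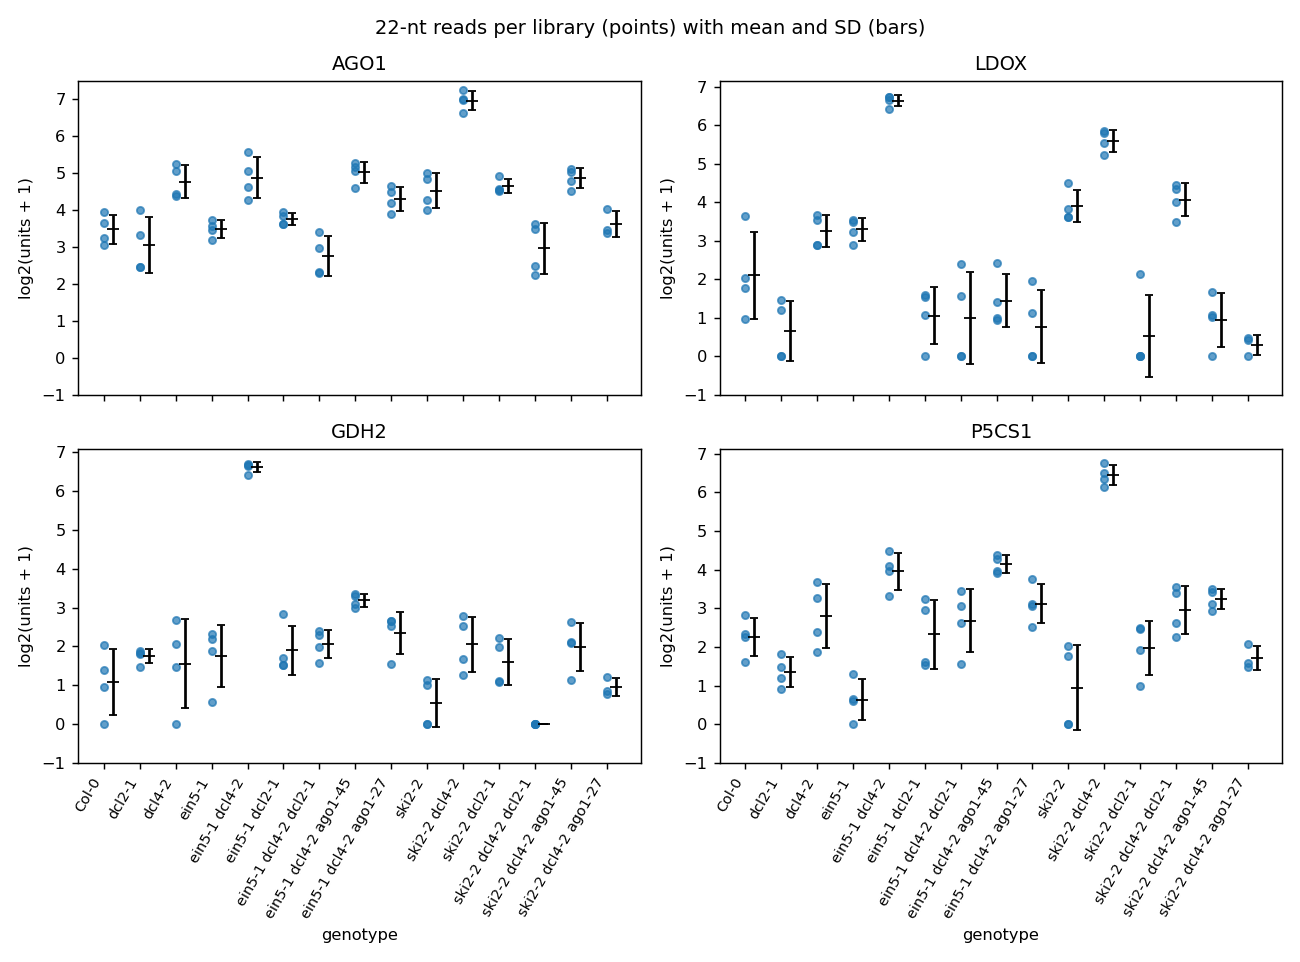
AGO1, LDOX, GDH2 and P5CS1 in each recovered library (points) of 15 genotypes, with mean and SD, as log2(units + 1). LDOX lies between 85.4 and 106 units in the libraries of ein5-1 dcl4-2, and P5CS1 between 69.97 and 108.0 units in those of ski2-2 dcl4-2.

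Gene families named before the values were seen give a wider view. All 8 genes of the SMXL family, which repress karrikin and strigolactone responses or act in the phloem, rose over Col-0 in ein5-1 dcl4-2 in the authors' deposited table (8 also when adjusted over the list alone, 7 after centring). SMXL4 rose by 9.27 there, SMXL7 by 8.77, SMXL3 by 6.61 and SMAX1 by 5.93 in the authors' deposited table. In ski2-2 dcl4-2 only 4 rose (5 over the list alone), among them SMXL4 and SMXL3 (9.79), while SMXL7 changed by −0.95 (adjusted p 0.531) and SMXL6 by 0.00 in the authors' deposited table. Of 47 targets of conserved microRNAs with a p-value, 27 rose and 0 fell in ein5-1 dcl4-2 and 33 rose and 0 fell in ski2-2 dcl4-2 in the authors' deposited table (28 and 35 over the list alone, and 18 up and 1 down in ein5-1 dcl4-2 after centring). The auxin response factor genes ARF6, ARF8 and ARF10 rose by 6.01, 3.89 and 3.64 in ein5-1 dcl4-2 and by 11.80, 7.35 and 10.44 in ski2-2 dcl4-2 in the authors' deposited table. The auxin receptor genes AFB2 and TIR1 rose by 4.70 and 2.99 in ein5-1 dcl4-2 and by 2.96 and 1.3 in ski2-2 dcl4-2 in the authors' deposited table. MYB33 (5.80 and 6.77) and TOE2 (4.48 and 4.98), targets of miR159 and miR172, rose in both by the authors' deposited table. Differences between the ein5-1 and ski2-2 backgrounds were not tested for SMXL7, AFB2 and the other members of these families.

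Among 18 factors of RNA silencing and decay, 3 rose in each of these double mutants (2 over the list alone and 1 after centring in ein5-1 dcl4-2, 3 over the list alone in ski2-2 dcl4-2). AGO2, an Argonaute of antiviral defence, rose from an authors' mean of 1.21 units to 202 in ein5-1 dcl4-2 and 4283 in ski2-2 dcl4-2, with log2 folds of 7.02 and 11.30 in the authors' deposited table (adjusted p 1.2e-28 and 4.6e-99). AGO1 rose by 1.34 and 3.47 in the authors' deposited table (adjusted p 8.6e-04 and 4.8e-35).

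Anthocyanin genes carried more 22-nt reads in both double mutants. Over Col-0, 8 of 10 rose in each (8 over the list alone and after centring in ein5-1 dcl4-2, 9 over the list alone in ski2-2 dcl4-2) in the authors' deposited table. PAP1, the MYB activator of the pathway, rose by 7.77 and 7.64 in ein5-1 dcl4-2 and ski2-2 dcl4-2 in the authors' deposited table (adjusted p 3.6e-64 and 8.7e-69). PAP2 rose by 8.35 and 6.58, DFR by 4.22 and 3.21, LDOX by 4.24 and 3.27 and CHS by 1.80 and 1.46 in the authors' deposited table. Of 12 stress and abscisic acid genes 7 rose in ein5-1 dcl4-2 (9 over the list alone, 7 after centring) and 9 in ski2-2 dcl4-2 (11 over the list alone) in the authors' deposited table. HSP101, which resolves protein aggregates after heat, rose by 7.09 in ein5-1 dcl4-2, and RD29B of the abscisic acid response by 6.81 in ski2-2 dcl4-2 (adjusted p 4.3e-08) in the authors' deposited table. Of 12 nitrate uptake and assimilation genes, 5 rose and 2 fell in ein5-1 dcl4-2 (6 and 2 over the list alone, 4 and 2 after centring) and 4 rose and 1 fell in ski2-2 dcl4-2 (6 and 2 over the list alone) in the authors' deposited table. NIR1, the nitrite reductase gene, rose by 4.59 and 2.39 and GLT1 by 6.31 and 11.99, while GLN2 fell by 1.1 and 1.02 in the authors' deposited table.

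Photosynthesis genes went the other way. Over Col-0 all 20 fell in ein5-1 dcl4-2 (20 over the list alone and after centring) and 17 fell in ski2-2 dcl4-2, where RBCS1A alone rose (17 over the list alone), in the authors' deposited table. RCA fell by 2.45 and 2.12 and PSBO1 by 2.2 and 1.70, whereas RBCS1A, a small subunit of Rubisco, changed by −2.61 and 0.51 in the authors' deposited table. Over ein5-1, 13 of these genes fell in ein5-1 dcl4-2 and LHCB1.5 rose (13 and 1 over the list alone, 20 and 0 after centring) in the authors' deposited table. LHCB1.3 had authors' means of 680.2 units in Col-0, 209.7 in ein5-1 and 273 in ein5-1 dcl4-2, so it was already lower in ein5-1. Over ein5-1, 38 chloroplast genes fell and 3 rose (45 and 3 over the list alone, 64 and 0 after centring) in the authors' deposited table. Over Col-0, of 88 chloroplast genes 67 fell in ein5-1 dcl4-2 (73 over the list alone, 86 after centring) and 42 fell in ski2-2 dcl4-2 with 3 higher (49 and 3 over the list alone) in the authors' deposited table. Of 27 protein-coding loci known for phased siRNAs, 11 rose and 11 fell in ein5-1 dcl4-2 (11 and 11 over the list alone, 8 and 12 after centring) and 9 rose and 11 fell in ski2-2 dcl4-2 (11 and 11 over the list alone) over Col-0 in the authors' deposited table. Over dcl4-2 these loci had 7 higher and 2 lower in ein5-1 dcl4-2 (also over the list alone, but 5 and 11 after centring) and 15 higher and 2 lower in ski2-2 dcl4-2 (16 and 2 over the list alone) in the authors' deposited table. MicroRNA loci had 26 higher and 14 lower of 150 in ein5-1 dcl4-2 (also over the list alone), but 14 higher and 38 lower after centring, and 33 higher and 10 lower of 147 in ski2-2 dcl4-2 (36 and 11 over the list alone) in the authors' deposited table. Mitochondrial genes had 6 higher and 6 lower of 120 in ein5-1 dcl4-2 (6 and 2 over the list alone), but 0 and 50 after centring, and 14 higher and 6 lower of 121 in ski2-2 dcl4-2 in the authors' deposited table. Floral marker genes such as SEP3 and AP1 have almost no reads, so that 0 of 8 and 0 of 7 called in the authors' deposited table says nothing of them, and of 8 trans-acting siRNA loci 0 are among the genes analysed.

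The genes affected in the ein5-1 and the ski2-2 background overlap. Of 11348 genes tested in both, loss of DCL4 raised 341 in each background where 197.9 would be shared if the backgrounds were independent (Fisher exact p 1.0e-33), and lowered 184 where 24.8 would be (exact p 4.4e-118). No library is shared between these comparisons. The counts under independence treat each tested gene as equally likely to be called. Calls depend on the number of reads of a gene in both backgrounds, so the excess and its p-values need not reflect shared effects alone. In the authors' deposited table the shared genes are 418 raised and 518 lowered. With limma they are 197 and 92 with a pseudocount of 0.1, 212 and 430 after quantile normalization and 183 and 481 on the scale of microRNA loci. For SMXL5 no difference between backgrounds was found (0.36 between folds of the authors' deposited table, SE 0.43, adjusted p 0.469, and −0.53 with the median shift taken off, adjusted p 0.233). Over the decay mutant, NIA1 and NIA2 rose more by 2.11 (SE 0.42) and 2.14 (SE 0.40) in the ein5-1 background (adjusted p 7.7e-07 and 1.2e-07 for a difference of folds in the authors' deposited table). Of this, 1.22 and 1.26 remain once the median shift of 0.88 is taken off (adjusted p 0.00467 and 0.00211). What remains depends on the reference, since ski2-2 alone had more NIA1 and NIA2 reads than ein5-1. Over Col-0 the folds of both genes differ between the double mutants by about the median shift of 0.93 there. This leaves little difference, though it was not tested. HSP70, CYP79B2 and HSC70-1 had higher folds with EIN5 lost (HSC70-1 8.1 over ein5-1, −0.24 over ski2-2), by differences of 10.24, 10.76 and 8.34 in the authors' deposited table. PHB, REV, ATHB8, PHV and GUN5 had higher folds in the ski2-2 background (GUN5 6.48 over ski2-2, −0.10 over ein5-1), by differences of −7.20, −8.16, −10.81, −6.67 and −6.57 in the authors' deposited table.

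The joint effect of both losses exceeded the sum of the single losses for GDH2 (interaction 4.41, SE 0.70, limma adjusted p 3.0e-05) and PCK1 (3.60, SE 0.43, limma adjusted p 6.7e-07) in the ein5-1 background. GT18 fell short of the sum by −1.20 (SE 0.42, limma adjusted p 0.0387), a call that 12 of 21 alternatives lose. In the ski2-2 background P5CS1 (4.95, SE 0.66), PYK10 (4.56, SE 0.71) and AGO1 (1.14, SE 0.36) exceeded it with limma adjusted p of 2.0e-07, 3.8e-06 and 0.0349, where AGO1 loses the call in 13 of 21 alternatives. VTC2, which commits sugars to vitamin C, fell short of the sum by −1.58 (SE 0.37, limma adjusted p 0.00278). For the ein5-1 background 2759 genes exceeded and 312 fell short of the sum among 15077, but 908 and 1119 after quantile normalization, since the median interaction is 0.83, and 1242 and 229 with a pseudocount of 0.1. For the ski2-2 background the numbers are 446 and 410 among 12159, and 278 and 246 with a pseudocount of 0.1. Targets of conserved microRNAs exceeded the sum in 10 of 33 and 12 of 30 cases (11 and 15 over the list alone) and fell short in 0 (0 and 2 over the list alone).

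Loss of DCL2 took these reads away again. NIA1 and NIA2 had authors' means of 228 and 242 units in ein5-1 dcl4-2 dcl2-1 and of 307 and 362 in ski2-2 dcl4-2 dcl2-1. As log2 folds of the double over the triple mutant, the authors' deposited table gives 10.53 and 10.37 in the ein5-1 background and 9.35 and 8.88 in the ski2-2 background. GTE7 (13.48), HSP70 (14.90) and SMXL5 (9.03) of ein5-1 dcl4-2 and GLT1 (10.10), PHB (10.25) and REV (10.35) of ski2-2 dcl4-2 depended on DCL2 as well in the authors' deposited table. SMXL4 depended on it by 9.14 and 10.03, AGO2 by 5.02 and 8.96, PAP1 by 7.64 and 6.51 and ARF6 by 3.05 and 9.46 in the authors' deposited table.

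Recovered libraries show this loss of LDOX by 5.65 log2 (SE 0.46, limma adjusted p 5.5e-11), GDH2 by 4.55 (SE 0.33, limma adjusted p 1.1e-11) and PKS1, a phototropism gene, by 4.68 (SE 0.44) in ein5-1 dcl4-2 dcl2-1 against ein5-1 dcl4-2. In ski2-2 dcl4-2 dcl2-1, AGO1 went from 124 to 7.44 units (−4.00, SE 0.30, limma adjusted p 1.4e-30). The pentatricopeptide repeat genes AT1G62910 and RPF3 fell by 5.38 (SE 0.39) and 4.47 (SE 0.38), with limma adjusted p of 2.1e-31 and 1.6e-24. Of the protein-coding loci of phased siRNAs, 20 of 23 fell when DCL2 was lost in the ein5-1 background and 12 of 19 in the ski2-2 background (20 and 15 over the list alone), and 0 rose. MIR850 does not follow DCL2 throughout. It was among the 10 genes of highest value with ago1-27 in both backgrounds, where DCL2 is in place. It was not among them in dcl2-1, ein5-1 dcl2-1, ski2-2 dcl2-1 or ski2-2 dcl4-2 dcl2-1. By the authors' means it stood at 4336 units in ein5-1 dcl4-2 dcl2-1 and 205 in ein5-1 dcl4-2, a log2 fold of −4.57 for double over triple in the authors' deposited table. MIR169g, which acts on NF-YA genes, rose by 3.39 (SE 0.33, limma adjusted p 1.4e-09). The photosynthetic genes PSAK and LHCB2.3 rose by 3.46 (SE 0.33) and 3.10 (SE 0.34) in that background, and LHCB2.3, PSAF, NPQ4 and the photorespiration gene AGT by 3.70 (SE 0.32), 2.98 (SE 0.29), 2.35 (SE 0.25) and 2.52 (SE 0.23) in ski2-2 dcl4-2 dcl2-1.

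When DCL2 was lost in the ein5-1 background, 514 genes rose and 3770 fell among 17758 in limma, around a median log2 fold of −0.68. After quantile normalization 1822 rose and 1662 fell, and 238 rose and 6595 fell on the scale of microRNA loci. In the ski2-2 background 1016 rose and 614 fell among 14150 around a median of 0.23, against 836 and 824 after quantile normalization and 625 and 1215 on the scale of microRNA loci, with totals of 1008 for a pseudocount of 0.1 and 2585 for all libraries in 1 fit. Chloroplast genes rose in 46 of 60 and 35 of 56 cases (48 and 45 over the list alone). MicroRNA loci in the ein5-1 background had 11 higher and 13 lower of 76 (13 and 14 over the list alone), which quantile normalization turns to 27 and 6. Over all 150 loci with a p-value, those too high to recover included, 12 were higher and 41 lower in ein5-1 dcl4-2 than in ein5-1 dcl4-2 dcl2-1 (13 and 43 over the list alone, 8 and 57 after centring) in the authors' deposited table.

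The double mutants serve both as the raised and as the reference group. Genes raised in each background were also compared with losses in the other, which share no library. Of genes raised in ski2-2 dcl4-2, 264 fell when DCL2 was lost in the ein5-1 background where independence gives 142.6 (Fisher exact p 5.4e-28). Of those raised in ein5-1 dcl4-2, 209 fell when DCL2 was lost in the ski2-2 background where independence gives 143.3 (exact p 5.0e-11). Both counts under independence again treat each gene as equally likely to be called, so the excess may in part follow read number. LDOX, AGO1 and P5CS1 belong to both sets, and LDOX fell by 1.53 (SE 0.31, limma adjusted p 3.3e-05) in ski2-2 dcl4-2 dcl2-1.

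The 4 libraries of Col-0 are shared by the comparisons of all 4 single mutants, so the fall of MIR845b in each of them is not 4 separate findings. It fell by 1.64 (SE 0.22) in dcl2-1, 1.63 (SE 0.22) in dcl4-2, 1.93 (SE 0.20) in ein5-1 and 3.07 (SE 0.29) in ski2-2, with limma adjusted p of 1.0e-10, 3.4e-11, 3.9e-15 and 5.5e-22. Without DCL2, reads rose on GRP7, an RNA-binding protein of the circadian clock, from 1.88 to 77.8 units (4.84, SE 0.31, limma adjusted p 1.1e-50). GRP7 does not follow DCL2 throughout, with authors' means of 68.8 units in ein5-1 and of 4.13 in ski2-2 dcl4-2 dcl2-1 against 32.5 in ski2-2 dcl4-2. MIR169d and MIR169g rose by 2.84 (SE 0.23) and 3.13 (SE 0.25) and PMDH2, a peroxisomal malate dehydrogenase gene, fell by 1.83 (SE 0.25). Of microRNA loci 25 rose and 1 fell in dcl2-1 of 73 (30 and 2 over the list alone, 17 and 3 on their own scale). In all 369 genes rose and 266 fell in dcl2-1 among 11102, and 116 rose and 1145 fell on the scale of microRNA loci. The total of 635 becomes 399 with a pseudocount of 0.1 and 190 with all libraries in 1 fit.

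Without DCL4, MIR843 rose from 6.20 to 77.4 units (3.46, SE 0.24, limma adjusted p 9.2e-42) and AFB2 from 14.9 to 74.2 (2.25, SE 0.20, limma adjusted p 1.5e-25). Phased siRNA loci rose in 8 of 13 cases and fell in 1 (10 and 1 over the list alone), and targets of conserved microRNAs in 8 of 28 (13 over the list alone). Phased siRNA loci above the recovered range went the other way, since AT1G63080 had an authors' mean of 858 units in Col-0 and 36.8 in dcl4-2, AT1G63400 821 and 27.0, AT1G62914 790.1 and 23.6, AT1G62910 338 and 26.1 and RPF3 306 and 20.8. In all 143 genes rose and 118 fell in dcl4-2 among 11480, and 89 rose and 459 fell on the scale of microRNA loci, with totals of 166 for a pseudocount of 0.1 and 82 for all libraries in 1 fit.

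Without EIN5, reads rose on AFB2 (1.77, SE 0.19, limma adjusted p 1.2e-14), on GT18 (3.35, SE 0.25, limma adjusted p 4.0e-25) and on the purine transporter gene AZG1 (4.25, SE 0.31, limma adjusted p 1.4e-25). The glycine-rich protein gene GRP-3 fell by 1.81 (SE 0.16) and GAPA-2 by 1.58 (SE 0.16), and chloroplast genes fell in 34 of 50 cases (42 over the list alone, 21 on the scale of microRNA loci). In all 891 genes rose and 475 fell in ein5-1 among 11637, and 1550 and 280 on the scale of microRNA loci, with totals of 907 for a pseudocount of 0.1 and 568 for all libraries in 1 fit. Without SKI2, the starch synthase gene GBSS1 rose from 12.1 to 64.2 units (2.40, SE 0.23, limma adjusted p 2.1e-21). MIPS1 of inositol synthesis (1.49, SE 0.18), the chaperone gene HSP81-3 (1.38, SE 0.19) and the defence gene LURP1 (1.64, SE 0.22) rose as well. The chaperonin gene CPN60B fell by 2.45 (SE 0.38) and the chloroplast RNA-binding protein gene RBP31 by 1.47 (SE 0.28), among 100 genes higher and 71 lower of 11637. This total of 171 becomes 74 with a pseudocount of 0.1, 69 with all libraries in 1 fit and 110 to 158 with a library left out.

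Taking DCL2 from the decay mutants with DCL4 in place lowered anthocyanin genes in both backgrounds (median limma log2 folds −1.87 and −2.04). This is not particular to the decay mutants, since the 4 anthocyanin genes tested in dcl2-1 against Col-0 had a median of −1.73. In ein5-1 dcl2-1 against ein5-1, reads rose on GRP-3 (2.05, SE 0.16, limma adjusted p 2.8e-33) and on the photosystem genes PSBW (1.68, SE 0.14), PSAG (1.66, SE 0.16) and PSAF (1.61, SE 0.16), and fell on VTC2 (−1.46, SE 0.20). PSBW, PSAG and PSAF were also higher in ski2-2 dcl2-1 than in ski2-2 by the authors' means, with 77.4 against 48.7, 61.7 against 29.7 and 61.3 against 33.4 units. Anthocyanin genes fell in 4 of 5 cases (5 over the list alone), and also in 4 of 5 in ski2-2 dcl2-1 (4 over the list alone). Of 5 photosynthesis genes tested in ski2-2 dcl2-1, 0 rose and 2 fell (1 and 3 over the list alone). Chloroplast genes rose in 3 of 63 cases there (0, with 17 lower, on the scale of microRNA loci), and in ein5-1 dcl2-1 in 37 of 60 cases (46 over the list alone, 16 after quantile normalization, 8 on the scale of microRNA loci). In ein5-1 dcl2-1, 874 genes rose and 316 fell among 13156, but 461 and 565 after quantile normalization and 380 and 917 on the scale of microRNA loci, around a median of 0.21. The total of 1190 becomes 788 with a pseudocount of 0.1 and 310 with all libraries in 1 fit. The lower recovery limit of ein5-1 (52.5 units, against 99.7 in ein5-1 dcl2-1) favours rises in this split.

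In ski2-2 dcl2-1 against ski2-2, the chlorophyll synthesis gene PORB rose from 3.68 to 70.6 units (4.30, SE 0.32, limma adjusted p 5.9e-38). In ski2-2 dcl4-2 dcl2-1, PORB has an authors' mean of 1.28 units. GRP7 rose by 3.58 (SE 0.32) and MIR845b by 2.82 (SE 0.32). GLT1 rose by 3.60 (SE 0.32) to 59.5 units, which is 0.0954% of its value in ski2-2 dcl4-2. GBSS1 fell by 4.8 (SE 0.36, limma adjusted p 1.6e-37), MIPS1 by 2.85 (SE 0.24) and the photorespiration gene GOX1 by 1.83 (SE 0.20). MicroRNA loci rose in 21 of 78 cases and fell in 0 (37 over the list alone, 11 and 4 on their own scale). In all 367 genes rose and 438 fell among 11869, but 131 and 1415 on the scale of microRNA loci, with totals of 454 for a pseudocount of 0.1 and 354 for all libraries in 1 fit.

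In the triple mutants with an ago1 allele, reads of NIA1 and NIA2 were low as well. The authors' means of NIA1 and NIA2 were 33.8 and 56.5 units in ein5-1 dcl4-2 ago1-45, 28.0 and 39.0 in ein5-1 dcl4-2 ago1-27, 6.01 and 9.59 in ski2-2 dcl4-2 ago1-45, and 14.7 and 9.74 in ski2-2 dcl4-2 ago1-27. GTE7 and GTE2 had authors' means of 66641 and 21145 units in ein5-1 dcl4-2 ago1-45 and 877 and 88.2 in ein5-1 dcl4-2 ago1-27, against 92714 and 50410 in ein5-1 dcl4-2. GLT1 and PHB had authors' means of 1663 and 515 units in ski2-2 dcl4-2 ago1-45 and 9.01 and 145 in ski2-2 dcl4-2 ago1-27, against 62348 and 56875 in ski2-2 dcl4-2. AT2G01021 is 0 in all 4 genotypes with ago1 and has 5994 to 22370 units by the authors' means in the other 11. Whether the 4 were processed apart is not stated, so a difference in processing between ago1 triple and double mutants stays open.

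LDOX fell by 5.20 (SE 0.33) and 5.87 (SE 0.41) in ein5-1 dcl4-2 ago1-45 and ago1-27 against ein5-1 dcl4-2, with limma adjusted p of 3.9e-22 and 2.4e-16, and GDH2 by 3.43 (SE 0.25) and 4.26 (SE 0.32). In the ski2-2 background CHS, the entry enzyme of flavonoid synthesis, fell by 4.85 (SE 0.29) and 5.83 (SE 0.29) with ago1-45 and ago1-27, with limma adjusted p of 5.2e-26 and 7.4e-15. AGO1 reads fell by 3.34 (SE 0.22) with ago1-27, and AT1G62910 by 2.32 (SE 0.20) with ago1-45. Reads rose on the light-harvesting genes LHCA1 and LHCA2 in ein5-1 dcl4-2 ago1-45 (2.74, SE 0.15, and 2.86, SE 0.17), on LHCB1.4 and GRP7 in ski2-2 dcl4-2 ago1-45 (2.19, SE 0.13, and 2.78, SE 0.16) and on PSAO and MIR395a in ein5-1 dcl4-2 ago1-27 (2.58, SE 0.26, and 2.74, SE 0.27). MIR172b rose from 1.19 units, which is 1 read in 1 library, to 232 units (7.22, SE 0.47, limma adjusted p 6.7e-13) and MIR167d by 1.86 (SE 0.15) in ski2-2 dcl4-2 ago1-27. Targets of conserved microRNAs fell in 20 of 37 cases with each allele in the ein5-1 background and in 19 of 31 with each in the ski2-2 background (20, 22, 19 and 21 over the list alone). In ein5-1 dcl4-2 ago1-45 the 20 lower become 7 on the scale of microRNA loci. The sum over these loci is itself 0.497 of that in Col-0 there and 0.656 in ski2-2 dcl4-2 ago1-45, against 1.079 and 1.372 in the double mutants. This scale thus differs with the genotype and is no neutral reference for the ago1 comparisons.

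For ein5-1 dcl4-2 ago1-45, 600 genes rose and 4057 fell among 18168 around a median of −0.66, against 1442 and 1283 after quantile normalization and 1745 and 1024 on the scale of microRNA loci. Phased siRNA loci had 1 higher and 3 lower of 23 there, which quantile normalization turns to 9 and 1. For ein5-1 dcl4-2 ago1-27 the numbers are 515 and 3138 among 18090 around −0.55, against 1382 and 1410 and 835 and 2044. For ski2-2 dcl4-2 ago1-45 they are 907 and 1886 among 13309 around −0.16, against 1404 and 1415 and 2653 and 745. For ski2-2 dcl4-2 ago1-27 they are 595 and 1037 among 11928 around −0.38, against 973 and 738 and 1162 and 699, and their total of 1632 ranges from 1058 to 2471 with a library left out. LDOX, GDH2, CHS and MIR172b keep their direction under each scale.

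The alleles ago1-45 and ago1-27, which are alike at AT2G01021, were compared with each other, a comparison added after the values were seen. Whole classes of low genes differ between them. The median log2 ratio of pseudogenes to Col-0 was −1.28 and −0.89 with ago1-45 in the ein5-1 and ski2-2 backgrounds, against −0.15 and 0.30 with ago1-27. Mitochondrial medians were lower with ago1-45 too, while protein-coding and chloroplast medians were higher. Processing that differs between the alleles thus stays open. In the ein5-1 background the guard cell gene FMA had 249 units with ago1-45 and 10.9 with ago1-27 (4.73, SE 0.24, limma adjusted p 3.7e-37). AFB2 and TGG1 were higher by 1.41 (SE 0.17) and 1.42 (SE 0.16), and MIR395a, of sulfate starvation, was lower by 3.91 (SE 0.26). In the ski2-2 background the thiamine gene THI1 (2.59, SE 0.11), GRP7 (3.43, SE 0.14) and PHV (1.92, SE 0.11) were higher and MIR163 and MIR172b lower by 2.17 (SE 0.13) and 3.39 (SE 0.17), all with limma adjusted p at or below 1.5e-14. MicroRNA loci had 8 higher and 37 lower of 85 and 4 higher and 48 lower of 93 (8 and 40, and 5 and 49, over the list alone), or 16 and 18, and 13 and 31, on their own scale. In all 987 genes were higher and 2112 lower among 15820, against 1345 and 1736 after quantile normalization and 3057 and 610 on the scale of microRNA loci, and 2451 and 2780 among 11649 around a median of 0.32, against 3179 and 964 on that scale. The totals of 3099 and 5231 become 1640 and 2703 with all libraries in 1 fit, and the second 3467 to 5249 with a library left out.

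**Figure D3:**
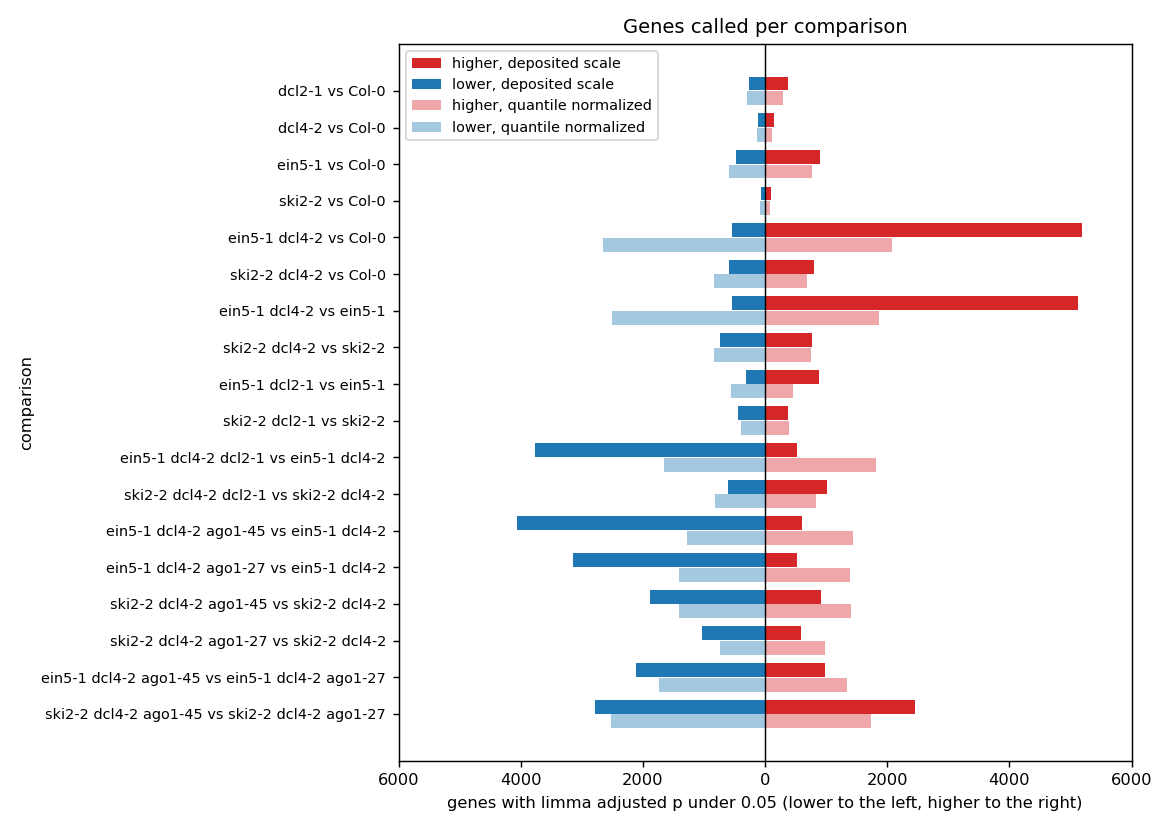
Genes called higher (right) and lower (left) by limma at adjusted p under 0.05 in 18 comparisons, on the deposited scale and after quantile normalization. In ein5-1 dcl4-2 against Col-0 they are 5179 and 545, and 2072 and 2648.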

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

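Tests chosen only after the result was seen are those of the shift between backgrounds, of words with mismatches, of scaling, of NIA1 above NIA2, of DCL2 dependence, of mRNA fragments, of the 6 genes of ski2-2 dcl4-2, of the ratio expected at their fraction in dcl2-1 library C, and of regrouped libraries. The search for shared 22-base words and the comparisons of genes particular to each double mutant were written before, the latter with a bound of 1.5 times, to which the expected ratio was added later.

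Differences between backgrounds were tested for 31 genes named in the double mutants, on folds of the authors' deposited table over the decay mutant alone, and 25 differ. The 31 genes were named for large changes in these same comparisons, so 25 of 31 does not measure how often genes differ between backgrounds. Higher with ein5-1 than with ski2-2 were NIA1 (by 2.11), NIA2 (2.14), GTE7 (8.39), DGAT3 (3.68), GTE2 (7.95), HSP70 (10.24), CYP79B2 (10.76), HSC70-1 (8.34), GAE6 (5.02), AK3 (1.48), AT3G43730 (0.77), ATCG00280 (0.52) and RCA (0.75). Lower were GLT1 (−5.98), PHB (−7.20), REV (−8.16), ATHB8 (−10.81), PHV (−6.67), SMXL4 (−1.45), GUN5 (−6.57), AT1G63080 (−1.39), AT1G63400 (−1.37), AT1G62914 (−1.52), AT1G62910 (−1.88) and AT1G63130 (−1.74). These folds over ein5-1 carry a median shift of 0.88 that those over ski2-2 lack. Without it, NIA1 and NIA2 differ by 1.22 and 1.26, AK3 (0.59), AT3G43730 (−0.11) and RCA (−0.13) no longer differ, and ATCG00280 turns to −0.37. The 1.22 and 1.26 depend on the reference, since ski2-2 alone has more NIA1 and NIA2 reads than ein5-1. Over Col-0 the folds of NIA1 and NIA2 differ between the double mutants by about the median shift of 0.93 there. Some differences are of size alone, since PHB, REV and PHV also rose by 4.62, 4.16 and 4.36 over ein5-1 and GTE7 and GTE2 by 2.85 and 2.83 over ski2-2 in the authors' deposited table, while HSC70-1 (−0.24) and GAE6 (−0.45) did not rise over ski2-2 nor GUN5 (−0.10) over ein5-1 there.

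A library stood far from the others of its genotype in 14 of 158 gene and genotype groups, and chance flags about 1 in 20 groups, or 8 here. In ski2-2 dcl4-2 these were MIR167d in library D (94.8 units, nearest 86.6), RPF3 in library A (74.4, nearest 96.3) and MIR172b in library D (4.74, nearest 0). In ein5-1 dcl4-2 they were GDH2 in library D (84.9, nearest 99.6) and TGG1 in library A (31.2, nearest 39.4). In ein5-1 dcl4-2 ago1-27 they were FMA in library C (26.8, nearest 6.70), GDH2 in library B (1.91, nearest 4.79) and TGG1 in library D (124.0, nearest 76.7). The rest were AGT in ski2-2 dcl4-2 dcl2-1 library D (99.6, nearest 113.0), LHCB1.4 in ski2-2 dcl4-2 ago1-45 library D (357.0, nearest 314.0), LHCA1 in ein5-1 dcl4-2 ago1-45 library D (295.0, nearest 244.0), MIR169g in dcl2-1 library C (80.3, nearest 65.8), and in Col-0 AZG1 in library A (3.25, nearest 1.04) and MIPS1 in library B (33.0, nearest 25.6).

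The rise of NIA1 and NIA2 in both double mutants was weighed against scaling and shared reads. Divided by the sums over microRNA loci, the lowest ratio to Col-0 is still 1596, which excludes the scaling of the columns. NIA1 lies above NIA2 by 160 times the ski2-2 value of NIA1 in ski2-2 dcl4-2, so its rise is not made of reads shared with NIA2. For NIA2, 0.0% of its 22-base words occur in NIA1 and 4.71% with up to 2 mismatches, which excludes shared reads spread over the transcript as the cause, though reads piled on such a stretch were not examined. The lowest ratio of double to dcl2-1 triple mutant is 466.6, as 22-nt siRNAs made by DCL2 would give.

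The general rise of low protein-coding genes in ein5-1 dcl4-2 was weighed for the 9137 genes with 0.5 to 5 units in Col-0, whose median log2 ratio is 1.33. It exceeds the higher of the medians of microRNA loci and mitochondrial genes by 0.86, which excludes scaling as its whole cause. Of the raised genes 5.66% share a 22-base word with one of the 100 genes of highest value, against 2.49% of the others, and with 1 mismatch 23.68% against 13.1%, so shared reads do not explain the rise of most of these genes but may add to some. The median falls by 1.19 when DCL2 is lost too, so most of the rise needs DCL2, directly or through other changes in the triple mutant. Counts of 22-nt reads alone cannot tell products of DCL2 from mRNA fragments that fall indirectly. What makes these reads with DCL2 was not tested further.

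Genotypes without DCL2 carry a few reads of the genes that peak in ski2-2 dcl4-2, and reads from ski2-2 dcl4-2 material were weighed as their source. PHB, REV, ATHB8, PHV, SMXL4 and SMXL5 hold nearly the same fraction of their ski2-2 dcl4-2 value in dcl2-1 library C (median 0.0742%, highest over lowest 1.5) and in ein5-1 dcl4-2 dcl2-1 (median 0.114%, 1.35), and also in ski2-2 dcl2-1 (1.26), less evenly in ski2-2 dcl4-2 dcl2-1 (2.08) and ein5-1 dcl2-1 (3.63), against 564 in dcl4-2 and 29.6 in Col-0, so such reads may be present at that level, and the rise of GLT1 in ski2-2 dcl2-1 (0.0954%) may belong to them. Reads from ein5-1 dcl4-2 at the same fraction do not explain library C, since 110 genes particular to that genotype have 0.9335 times (counting SE 0.12) the units of the highest other dcl2-1 library, where 1.49 would follow. The planned comparisons of genes particular to ski2-2 dcl4-2 decide nothing, with 1.945 for dcl2-1 library C and 0.3589 for ein5-1 dcl2-1 libraries C and D on 2 genes. In ein5-1 dcl4-2 dcl2-1, NIA1, NIA2 and GLT1 stand at 0.114%, 0.143% and 0.161% of their ski2-2 dcl4-2 values. Reads at the 0.114% of the 6 genes could thus be most or all of those left there. In ski2-2 dcl4-2 dcl2-1 they stand at 0.154%, 0.214% and 0.0851%, where the 6 genes have 0.0526 to 0.109%. Whether the reads left in the dcl2-1 triple mutants are such reads was not tested. No biological explanation was tested, and where the reads would have mixed stays open.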

How the results depend on the processing

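The recovery of library values, the filter at a mean of 1 unit, the calls and centred folds (and centred differences) of the authors' deposited table, the comparison of ago1-45 with ago1-27 and the removal of ein5-1 dcl2-1 libraries C and D were chosen after the data were seen. For genes named from limma, 1265 of 1290 alternative values kept direction and side of the threshold, 25 kept direction and lost the threshold (17 of them with a library left out), and 0 reversed. The 25 belong to 2 interactions, that of GT18 in the ein5-1 background (12 of 21 alternatives, adjusted p up to 0.163) and that of AGO1 in the ski2-2 background (13 of 21, up to 0.313), both from limma. The 160 folds named from the authors' deposited table were chosen with a size of at least 1, and the largest median is 0.93. Centring on the median therefore could not reverse them, and their unchanged direction is no test. Centred differences between backgrounds changed sign for 8 genes, AT3G43730 (−0.11), ATCG00280 (−0.37), RCA (−0.13), SMXL5 (−0.53), AT1G18010 (−0.68), AT1G18000 (−0.66), AT2G07732 (−0.76) and ATCG00680 (−0.78), the last 2 now past the threshold with ATCG00490 (−0.89), as the shift of 0.88 is taken off by construction, and AK3 (0.59), AT3G43730 and RCA lost it. Of 375 alternative counts, 331 lay within 1.5 times the reported count.

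With a pseudocount of 0.1 the counts were lower: dcl2-1 399, dcl4-2 166, ein5-1 907 and ski2-2 74 against Col-0, ski2-2 dcl4-2 899 against Col-0 and 919 against ski2-2, ein5-1 dcl2-1 788, ski2-2 dcl2-1 454, ski2-2 dcl4-2 dcl2-1 1008, and interactions 1471 and 524. Overlaps became 197 raised and 92 lowered genes, and 157 genes raised in ski2-2 dcl4-2 and lowered in the other background. With all 59 libraries fitted together the counts were dcl2-1 190, dcl4-2 82, ein5-1 568, ski2-2 69, ein5-1 dcl2-1 310, ski2-2 dcl2-1 354, ski2-2 dcl4-2 dcl2-1 2585, ago1-45 against ago1-27 1640 and 2703 in the ein5-1 and ski2-2 backgrounds, and 335 genes raised in ein5-1 dcl4-2 and lowered in the other background. Scaled by microRNA loci they were dcl2-1 1261, dcl4-2 548, ski2-2 dcl2-1 1546, ein5-1 dcl4-2 dcl2-1 6833 and ein5-1 dcl4-2 ago1-45 2769, with overlaps of 183 raised and 481 lowered. Quantile normalization gave 2725 for ein5-1 dcl4-2 ago1-45, 2027 for the ein5-1 interaction, and overlaps of 212 raised, 430 lowered and 168 raised in ski2-2 dcl4-2 and lowered in the other background. The authors' deposited table gave 518 shared lowered genes and 319 raised in ein5-1 dcl4-2 and lowered in the other background. The cause of these changes was not tested, except that scaling by microRNA loci shifts all genes of a library together. Without the filter 0 of 24 counts moved beyond 1.5 times.

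With a library left out, ski2-2 against Col-0 ranged from 110 to 158 genes, with 110 and 112 without Col-0 libraries A and B. For ski2-2 dcl4-2 ago1-27 the range is 1058 to 2471, with 1058 and 1065 without its libraries B and C and 2471 without ski2-2 dcl4-2 library D. For ago1-45 against ago1-27 in the ski2-2 background it is 3467 to 5249, with 3467 without ago1-27 library B. The other counts stayed within 1.5 times. Without libraries C and D, ein5-1 dcl2-1 gave 959 genes.

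No paired analysis was possible because the columns carry no replicate numbers. Not run were the count tools, as the deposited unit is a mean of scaled signal and the recovered reads leave out the highest genes, the share of trans-acting siRNA loci, and permutation or omission of libraries for the shares, since NIA1 and NIA2 have no recovered libraries in the double mutants. Depth limits the low genes most, as 1 read is worth up to 4.74 units.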

Other observations

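Some genes of nitrogen use and the SMXL family behave apart from the sets described so far, and were chosen after their values were seen. SMXL5 and SMXL4 already had authors' means of 879 and 173 units in dcl4-2, against 20.7 and 13.5 in Col-0. UPM1, which makes the siroheme that nitrite reductase needs, rose by 6.03 in ein5-1 dcl4-2 and by 0.61 (adjusted p 0.792) in ski2-2 dcl4-2 over Col-0 in the authors' deposited table. SMXL7 was lower in ski2-2 dcl4-2 than in its dcl2-1 triple mutant by 2.45 (adjusted p 0.0171) in the authors' deposited table, opposite to its fold of 7.56 in the ein5-1 background. These differences between backgrounds were not tested.

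Whether chance could give as many genes was tested by regrouping the libraries, with all of these tests written after the counts were seen. In each of the 18 comparisons 1 of 35 splits, the real grouping itself, gave as many genes. This is the lowest share that 35 splits can give. The other splits mix libraries of genotypes that differ, which widens the spread within groups, so the first rank of the real grouping says little. In each of the 2 interactions 1 of 100 groupings gave as many. Regrouping there also breaks up the effects of the single losses, so it does not test the interaction alone. Chance is therefore not excluded by these tests. The real and the highest other counts are 635 and 18 for dcl2-1, 261 and 15 for dcl4-2, 1366 and 0 for ein5-1, 171 and 11 for ski2-2, 5724 and 0 for ein5-1 dcl4-2 and 1395 and 1 for ski2-2 dcl4-2 against Col-0. Against the decay mutant they are 5670 and 0 for ein5-1 dcl4-2, 1514 and 10 for ski2-2 dcl4-2, 1190 and 1 for ein5-1 dcl2-1 and 805 and 16 for ski2-2 dcl2-1. For dcl2-1 triple mutants they are 4284 and 0 and 1630 and 11 in the ein5-1 and ski2-2 backgrounds, for ago1-45 triple mutants 4657 and 0 and 2793 and 0, for ago1-27 triple mutants 3653 and 0 and 1632 and 306, and for ago1-45 against ago1-27 3099 and 7 and 5231 and 511. For the interactions they are 3071 and 2510 with ein5-1 and 856 and 174 with ski2-2.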
